A study of Mus musculus with 15 samples.

How the data were processed

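Gene expression was measured on oligonucleotide arrays, 1 array per sample, in 9 mouse peripheral T cell lymphomas, 3 resting and 3 activated T cell samples. Per the labels' protocols, RNA was extracted with a column kit, and RNA of the normal cells was amplified with a 3′ in vitro transcription kit; the kit for the lymphomas is not given in the sources used here. The deposited values are intensity on a linear scale, which the authors computed per the labels with MAS5 in Affymetrix Expression Console, version 1.1 for the lymphomas and of a version not given for the normal cells. The 2% trimmed mean was 500 in every array, as tested on the values. No detection calls were used. The arrays' number limits the precision.

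Groups came from the labels, and the comparisons were activated against resting T cells, lymphomas against resting T cells and lymphomas against activated T cells. Values below 32 were set to 32 (5 on the log2 scale) and log2 was taken. Of the probe sets, 34958 were listed with 1 gene symbol, 932 with several and 9211 with none. Those with 1 symbol were used, without the 64 controls, which are counted among these classes. Symbols of 34754 were updated by gene identifier. Each of 18193 genes was represented by its probe set with the highest mean, and the 11920 genes with at least 100 in at least 3 arrays were tested. Fold changes against a group with arrays at the floor are lower bounds where the other group has none there. The deleted p53 gene itself is not analysed here.

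Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend, fitted to the arrays of the groups compared. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Genes were grouped in 32 lists with 685 members, 604 of them on the array, written before the data were examined, as were the comparisons, the rule for naming genes and the first set of alternatives. The lists cover T and NK cell programmes, the cell cycle, metabolism, responses, and markers of other cells. They were tested with camera at a correlation of 0.01 and again with an estimated correlation, and with fry. Adjustment was over the 32 lists of a comparison. A change called in both lymphoma comparisons in the same direction set a gene apart from both normal states. The number to be found if no gene changed came from 50 simulations of unchanged groups with shared arrays. Relations across the 9 lymphomas used list means, Pearson's r and Spearman's rho, with 2-sided exact permutation tests, 9 relations in all. The fits were tested on simulated data with known changes.

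Genes were named by rule. Per comparison these were the 6 largest increases and 6 largest decreases among called genes whose groups did not overlap, without controls, predicted or clone-named genes, sex-linked genes and receptor gene segments. Per list they were at most 4 called members with the largest changes, at most 3 per direction. For both normal states they were the 8 higher and 8 lower genes with the largest smaller change. A fixed set was always given: Cd3e, Cd4, Cd8a, Klrd1, Klrk1, Ncr1, Tyrobp, Fcer1g, Syk, Zap70, Bcl11b, Zbtb16, Gzmb, Il2rb, Mki67 and Alb.

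The alternatives were floors of 16 and 64, log2 of the value plus 16, no filter, a filter at 200, quantile normalisation, centring on the median, the mean of a gene's probe sets, leaving out probe sets that match several transcripts, all 15 arrays in 1 fit, no trend, array weights per group, the adjusted p alone, a replicate block, the list tests named above, and leaving out each array. After the data were seen, the fits were repeated without 6 lymphomas whose neutrophil marker mean lay more than 2 log2 units above the highest normal array, and without 3 whose B cell marker mean lay more than 1 above it.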

Results

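Gene expression was measured in 15 mouse samples, each on 1 oligonucleotide array. The samples were 9 peripheral T cell lymphomas (mPTCL 1 to 9), 3 preparations of resting T cells and 3 of T cells activated in culture. The lymphomas arose in C57BL/6 mice lacking CD3, the signalling part of the T cell receptor (TCR), after these received T cells without p53, a transcription factor that stops or kills damaged cells. The lymphoma cells were sorted from liver. The normal T cells came from 5-week-old p53-null C57BL/6 mice and were sorted from liver or spleen, with no source organ stated per sample. The growth protocol of the normal samples describes repeated injections of saline or heat-killed pneumococci, and it is not stated whether these donors received either. The labels do not say whether replicates came from separate animals, so the p-values measure the spread among these samples, which may be partly technical.

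All arrays had the same 2% trimmed mean signal, 500. Their median signal was 94.5 ± 4.06 (SD, n = 3) in resting cells, 115 ± 3.98 (n = 3) in activated cells and 89.1 ± 15.5 (n = 9) in lymphomas. Pearson correlations between arrays of 1 group, across 11920 genes, ran from 0.968 to 0.976 in resting cells, from 0.970 to 0.974 in activated cells and from 0.761 to 0.924 in lymphomas. The median SD of a gene was 0.23, 0.19 and 0.60 on the log2 scale in the same order, and the small number of normal arrays limits the precision of every comparison. RNA controls differed between the groups. The ratio of 3′ to 5′ actin signal, which grows with RNA degradation, averaged 1.35 ± 0.13 (SD, n = 3) in resting cells, 1.52 ± 0.03 (n = 3) in activated cells and 1.93 ± 0.40 (n = 9) in lymphomas. The same ratio for Gapdh ran in another order, at 2.02 ± 0.18, 1.31 ± 0.05 and 1.85 ± 0.30. Added poly-A control RNAs averaged 10.96 ± 1.17, 9.45 ± 0.17 and 7.94 ± 0.31 on the log2 scale. The labels state no processing batch, but a software version is given for the lymphomas alone. If arrays are parted by that, 0 of 2 sets hold both, so any such batch and the group cannot be told apart where lymphomas are compared with normal cells.

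The first comparison addressed what activation in culture changed in normal p53-null T cells. Genes of cell division rose together. All 29 measured genes of G2 and M phase were higher in activated than in resting cells (29 adjusted over the list alone), among them Cenpf, a kinetochore protein, by 4.78 ± 0.28 log2 units (SE, n = 3 and 3; 27.5-fold, limma adjusted p = 1.93e-04), and Mki67, a marker of cycling cells, by 4.17 ± 0.20 (18.0-fold, adjusted p = 9.68e-05). Of 30 genes of S phase and DNA replication, 15 rose (15 adjusted over the list alone) and 15 did not pass, with thymidine kinase Tk1 at 3.06 ± 0.26 and Uhrf1, which keeps DNA methylation through replication, at 2.88 ± 0.15. Of 15 glycolysis genes, 14 rose (14 adjusted over the list alone): the lactate exporter Slc16a3 by 5.86 ± 0.23 (58.1-fold), triose phosphate isomerase Tpi1 by 3.38 ± 0.12 and hexokinase Hk2 by 2.98 ± 0.32. Adjusted p-values of the set test camera were 7.08e-26, 6.26e-10 and 5.95e-12 for these lists, and 0.131, 0.142 and 0.131 with an estimated correlation.

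Other genes with the largest increases were the mitochondrial adenylate kinase Ak4, at least 89.9-fold higher, the aldolase Aldoc (43.4-fold) and the collagen-modifying enzyme Plod2 (at least 42.4-fold). The mitophagy gene Bnip3 (34.8-fold) and the haematopoietic nuclear protein Hemgn (at least 31.5-fold, with 2 of 3 resting arrays at the floor) also rose, with adjusted p from 2.06e-05 for Ak4 to 1.50e-04 for Hemgn. The largest decreases were in the immediate early gene Fos, which fell by 5.17 ± 1.08 log2 units (adjusted p = 0.0134), the lysozyme gene Lyz1 (-4.42 ± 0.70), the Notch pathway gene Dtx1 (-3.96 ± 0.29), the homing receptor Ccr9 (-3.81 ± 0.26), Ears2 (at least 13.3-fold lower) and Prag1 (-3.72 ± 0.62). The call of Fos was lost without resting replicate 3 (adjusted p = 0.0527) or without activated replicate 3 (0.0557).

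The list of Myc and ribosome biogenesis genes moved down, with 13 of 24 members lower (13 adjusted over the list alone). Rrp9, a ribosomal RNA processing factor, fell by 2.35 ± 0.18 log2 units, Ppan by 1.94 ± 0.25 and spermidine synthase Srm by 1.47 ± 0.18. Camera gave the list an adjusted p of 7.66e-07 (adjusted p = 0.131 with an estimated correlation). Of 19 cholesterol synthesis genes, 7 rose (7 adjusted over the list alone), including Hmgcs1, which acts early in the pathway, by 1.66 ± 0.19. In camera the list had an adjusted p of 6.79e-05 (adjusted p = 0.544 with an estimated correlation). Immediate early genes, which respond first to stimulation, fell in 9 of 22 cases (10 adjusted over the list alone), with Egr1 at -2.53 ± 0.13, while Ier3 (1.38 ± 0.24) and Fosl2 (1.24) rose. For this list, the camera adjusted p was 0.0057 (adjusted p = 0.428 with an estimated correlation). No oxidative phosphorylation gene of 25 changed by 2-fold in limma, although Cyc1 (-0.69, adjusted p = 0.0023) and Cox7a2 (-0.90, adjusted p = 0.0494) passed the adjusted p and camera called the list lower (mean -0.27, 9 genes at an unadjusted p under 0.05; adjusted p = 0.0095; adjusted p = 0.579 with an estimated correlation; fry 0.104). That list call was lost after quantile normalisation (adjusted p = 0.107) and without resting replicate 1 (0.0606).

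Among genes of T cell identity, Cd3e was at 11.54 ± 0.08 in resting and 11.18 ± 0.19 in activated cells on the log2 scale (SD, n = 3 each), and none of the 7 TCR and CD3 genes passed the limma test at 2-fold or the test adjusted over the list alone (4 at an unadjusted p under 0.05; camera adjusted p = 0.360, fry 0.0719). Cd4 (-0.53 ± 0.12, adjusted p = 0.0163) and Cd8a (0.45 ± 0.12, adjusted p = 0.0339) differed by less than 2-fold. Zap70, the kinase of the TCR, changed by -0.26 ± 0.15 (adjusted p = 0.235) and Bcl11b, a factor that holds T cell fate, by 0.06 ± 0.09 (adjusted p = 0.649). Of 25 genes of IL-2 and IL-15 receptors and JAK-STAT signalling, 9 rose (9 adjusted over the list alone), with Il12rb2 at 4.61 ± 0.34, the IL-2 receptor chains Il2ra at 2.72 ± 0.39 and Il2rb at 1.72 ± 0.17, and Il18r1 was 2.15-fold lower. The set test camera returned an adjusted p of 8.80e-04 (adjusted p = 0.544 with an estimated correlation). Of 17 innate-like and natural killer (NK) cell transcription regulators, 8 rose, led by Bhlhe40 (4.19 ± 0.55) and Nfil3 (2.91 ± 0.33), and Sox4 fell by 1.11 ± 0.11 (the same counts adjusted over the list alone). Sox4 was not called with the mean of probe sets (limma adjusted p = 0.0980). Tested with camera, the list reached an adjusted p of 0.0095 (adjusted p = 0.299 with an estimated correlation). Of 23 genes of naive and quiescent T cells, Ramp1 (-2.53 ± 0.25), Atp1b1 (-1.88 ± 0.13) and Igfbp4 (-1.84 ± 0.19) fell (3 adjusted over the list alone). By camera its adjusted p was 0.0052 (adjusted p = 0.544 with an estimated correlation, and 0.198 with all 15 arrays in 1 fit).

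Cytotoxic genes moved both ways. Granzyme B, Gzmb, rose by 4.71 ± 0.44 (26.2-fold, adjusted p = 8.52e-04), Gzma by 2.22 ± 0.47 and the granzyme inhibitor Serpinb6b by 1.87 ± 0.14, while the chemokine Xcl1 fell by 1.97 ± 0.34 and perforin, Prf1, by 1.80 (3 higher and 3 lower of 20 adjusted over the list alone). Camera gave the list an adjusted p of 0.766. Of 20 NK cell receptor genes, Klrk1, which encodes NKG2D, rose by 2.31 ± 0.21 and Slamf7 by 2.29 ± 0.26, and Klra8 (-1.51 ± 0.34) and Klrg1 (-1.35 ± 0.32) fell (the same counts adjusted over the list alone). In camera the list had an adjusted p of 0.766. Klrd1, which encodes CD94, differed by 0.96 ± 0.17 (adjusted p = 0.0081), under 2-fold, and Ncr1 was at 5.77 in resting cells and at the floor of 5 in activated cells (adjusted p = 0.129). Ctla4 rose by 3.94 ± 0.20 and Lag3 by 2.97 ± 0.37, both inhibitory receptors, while Egr2 and Egr3 fell by 2.80 ± 0.31 and 3.12 ± 0.41. The adaptor Tyrobp fell by 1.97 ± 0.28, from 7.21 to 5.24, beside Fcer1g (-0.40 ± 0.31, adjusted p = 0.377) and Syk (-0.99 ± 0.73, adjusted p = 0.344). Zbtb16, the factor of innate-like T cells, was at 6.21 and 6.63 (adjusted p = 0.313).

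Markers of other cells differed too. Of 18 macrophage and Kupffer cell markers, 10 fell in activated cells (11 adjusted over the list alone), such as Csf1r by 3.51 ± 0.38 and C1qa, at least 10.5-fold lower. For this list, the camera adjusted p was 4.05e-05 (adjusted p = 0.387 with an estimated correlation). Of 11 endothelial and stromal markers, Dcn (at least 10.7-fold higher), Sparc (at least 6.38-fold), Col3a1 (at least 5.86-fold), Col1a2 and Bgn rose (5 adjusted over the list alone; camera adjusted p = 0.0095; adjusted p = 0.428 with an estimated correlation, and 0.0613 after quantile normalisation). Col1a2 and Bgn, like Prf1 and Fosl2, stood outside the naming rule and were named after their values were seen. The calls of Gzma (adjusted p = 0.0576 without resting replicate 3), Klra8 (0.0581 and 0.0598 without activated replicates 1 and 2) and Klrg1 (0.0597 without resting replicate 1; 0.0686, 0.0658 and 0.0554 without activated replicates 1, 2 and 3) were lost with 1 array fewer, though the changes moved little (2.02 for Gzma, -1.45 and -1.31 for Klra8, and -1.28 to -1.43 for Klrg1). Il18r1 was lost without resting replicate 2 or activated replicate 2 or 3 (0.0513 in the last). Hepatocyte markers held no called gene of 5, and albumin, Alb, was at 5.62 and 6.22 (adjusted p = 0.105).

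In limma, 1510 of 11920 genes were called in this comparison, 1006 higher and 504 lower in activated cells, and camera called 12 of 32 gene lists. After quantile normalisation 847 were higher and 648 lower. When all 15 arrays entered 1 fit, whose spread includes that of the lymphomas, 398 of the 1510 calls were kept, all in the same direction. Those of Gzmb (adjusted p = 0.221), Ctla4 (0.172) and Il2ra (0.523) were among the lost ones.

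**Figure D1:**
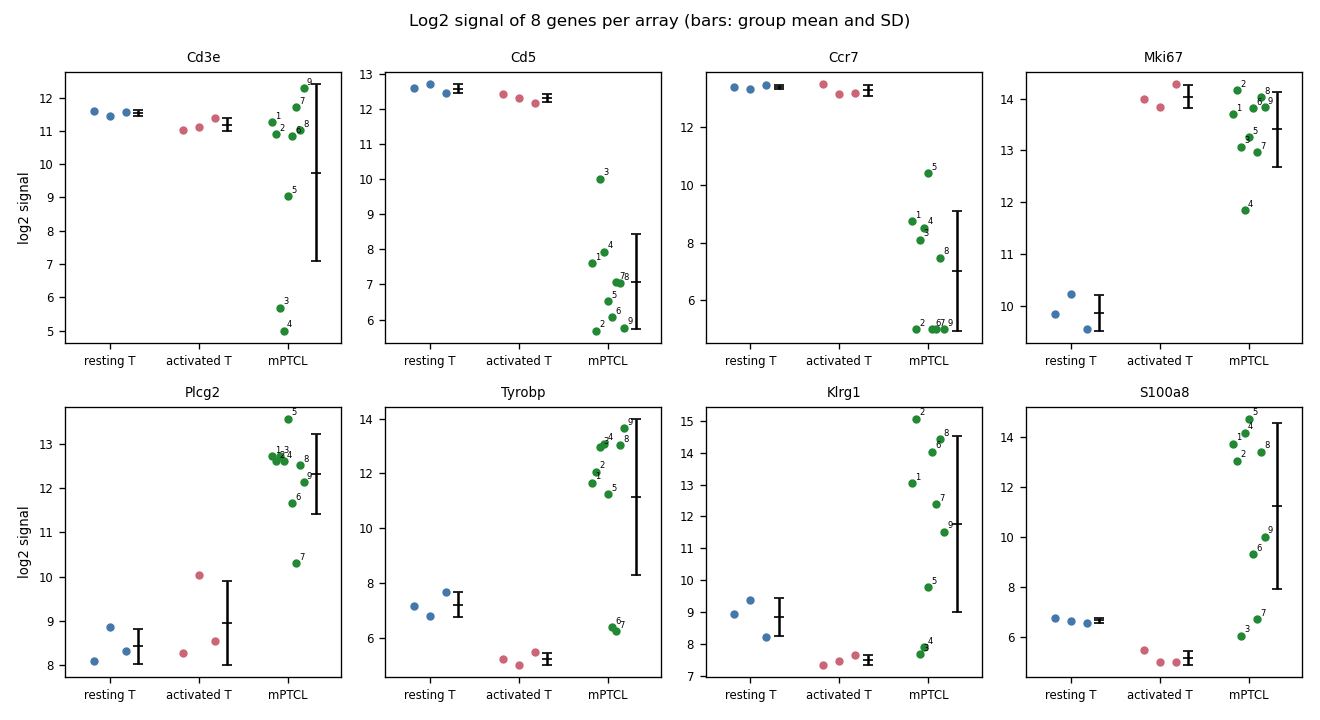
Signal of 8 genes on the log2 scale (vertical axis) in each of the 15 arrays, grouped as resting T cells, activated T cells and mPTCL; points are arrays, and bars give the mean and SD of a group. Cd5 and Ccr7 lay at 12.58 and 13.39 in resting cells and at 7.08 and 7.03 in lymphomas, while Klrg1, Tyrobp and S100a8 spread widely among the lymphomas.

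The comparison of the 9 lymphomas with resting T cells addressed how the lymphomas differ from unstimulated cells of the same genotype. Genes of the T cell receptor and of its signalling fell. Of 7 TCR and CD3 genes, 6 were lower in lymphomas (6 adjusted over the list alone): the coreceptor gene Cd8b1 fell by 5.99 ± 0.81 log2 units (SE, n = 9 and 3; 63.7-fold, limma adjusted p = 4.50e-04), Cd4 by 4.47 ± 1.24 (0.0259) and Cd8a by 3.50 ± 0.92 (0.0205). By camera its adjusted p was 4.92e-04 (adjusted p = 0.283 with an estimated correlation). Cd3e was at 11.54 ± 0.08 in resting cells (SD, n = 3) and 9.75 ± 2.65 in lymphomas (SD, n = 9), a difference that did not pass (-1.79 ± 1.38, adjusted p = 0.390). Its low values were those of mPTCL 3, 4 and 5 (5.7, 5 and 9.0). The other lymphomas ran from 10.8 to 12.3, against 11.4 to 11.6 in the resting arrays. Of 27 proximal TCR signalling genes, 7 fell (9 adjusted over the list alone), including the TCR regulators Cd5 (-5.50 ± 0.73, adjusted p = 3.96e-04) and Cd6 (-4.81 ± 0.79) and the costimulatory receptor Cd28 (-4.51 ± 0.96). Camera gave the list an adjusted p of 3.23e-07 (adjusted p = 0.105 with an estimated correlation). Zap70, at 12.40 in resting cells and 9.99 ± 2.11 in lymphomas (SD, n = 9; adjusted p = 0.146), and Bcl11b (-2.69 ± 0.88, adjusted p = 0.0505) did not pass.

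Genes of naive and quiescent T cells fell in 15 of 23 cases (19 adjusted over the list alone). The lymph node homing receptor Ccr7 fell by 6.36 ± 1.09 log2 units (82.2-fold, adjusted p = 0.0019), and Dapl1 stood at the floor in all 9 lymphomas, at least 58.6-fold lower (adjusted p = 7.95e-09). The list's camera adjusted p was 8.37e-11 (adjusted p = 0.105 with an estimated correlation). Other large decreases were in Tdrp (-6.71 ± 0.34, at least 105-fold, with 6 of 9 lymphomas at the floor) and Tmie, at the floor in all 9 lymphomas and at least 78.6-fold lower (adjusted p = 5.94e-09). Igfbp4 was 61.7-fold lower (adjusted p = 0.0032).

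Cell division genes rose. Of 30 genes of S phase and DNA replication, 26 were higher in lymphomas (27 adjusted over the list alone), with Tk1 at 4.21 ± 0.49 and the cyclin gene Ccne2 at 3.55 ± 0.51. The set test camera returned an adjusted p of 4.68e-17 (adjusted p = 0.399 with an estimated correlation). Of 29 G2 and M phase genes, 28 rose (28 adjusted over the list alone), with the mitotic kinases Aurkb at 4.12 ± 0.55 and Bub1 at 3.96 ± 0.56. Tested with camera, the list reached an adjusted p of 2.03e-23 (adjusted p = 0.299 with an estimated correlation). Mki67 rose by 3.54 ± 0.40 (adjusted p = 1.88e-04) and E2f8, a cell cycle transcription factor, by 5.68 ± 0.44 (51.4-fold, adjusted p = 1.16e-05). Smaller rises were called in the Myc and ribosome biogenesis list, where Odc1 (1.36 ± 0.37) and Rrs1 (1.12 ± 0.24) passed of 24 genes. The same held for the glycolysis list, where Slc16a3 (2.85 ± 0.45), Tpi1, Hk2, Slc2a1 and Pgam1 passed of 15, and for the oxidative phosphorylation list, where Uqcrfs1 (1.16 ± 0.18), Sdhb and Ndufa4 passed of 25. These counts were 2, 5 and 3 adjusted over the list alone, and the camera adjusted p-values 0.0047, 0.0216 and 2.78e-04 (adjusted p = 0.840, 0.729 and 0.729 with an estimated correlation). None of these lists passed fry (adjusted p = 0.260, 0.0749 and 0.0553).

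Of 27 interferon response genes, Usp18 (-3.45 ± 0.70), Ifit1 (-3.13 ± 0.76), Ifit3 (-2.16 ± 0.70) and Irf9 (-1.70) fell (3 adjusted over the list alone). In camera the list had an adjusted p of 0.0032 (adjusted p = 0.762 with an estimated correlation). Of 25 IL-2, IL-15 and JAK-STAT genes, 6 fell (7 adjusted over the list alone), among them the receptor gene Il21r by 2.23 ± 0.25 (adjusted p = 1.83e-04) and Stat5b by 2.17 ± 0.47, while the list did not pass camera (adjusted p = 0.0579) but passed fry (0.0323). Il2rb, shared by the IL-2 and IL-15 receptors, was at 11.43 in resting cells and 11.24 in lymphomas (adjusted p = 0.858).

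NK-related genes varied between lymphomas. Of 20 NK cell receptor genes, none passed limma, over all genes or adjusted over the list alone, and the list did not pass camera (mean 0.89, 3 genes at an unadjusted p under 0.05; adjusted p = 0.284) or fry (0.433). Klrd1 was at 13.22 in resting cells and 11.09 ± 3.12 in lymphomas (SD, n = 9; adjusted p = 0.382), Klrk1 at 8.96 and 9.21 ± 3.01 (adjusted p = 0.932), and Ncr1 at 5.77 and 7.93 ± 2.64 (adjusted p = 0.302). Of 20 cytotoxic genes, Gzma rose by 4.11 ± 0.87 (17.3-fold, adjusted p = 0.0066) and Xcl1 fell by 1.90 ± 0.52 (the same counts adjusted over the list alone), while Gzmb, at 8.28 in resting cells and 11.80 ± 3.16 in lymphomas, did not pass (adjusted p = 0.156). Among 17 innate-like and NK transcription regulators, Bhlhe40 (4.33 ± 0.57, adjusted p = 3.96e-04), Id2 (1.42 ± 0.38) and Runx3 (1.05 ± 0.31) rose and Ets1 fell by 1.51 ± 0.36 (4 higher and 2 lower adjusted over the list alone). By camera its adjusted p was 0.342. Zbtb16 differed by 0.91 ± 0.80 (adjusted p = 0.455).

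Among 8 NK receptor adaptors and kinases, Plcg2, a phospholipase used by B and NK cell receptors, rose by 3.91 ± 0.50 (15.0-fold, adjusted p = 3.42e-04) and Sh3bp2 by 1.42 ± 0.39 (3 higher and 1 lower adjusted over the list alone). Camera gave the list an adjusted p of 0.0598. Tyrobp (3.94 ± 1.48, adjusted p = 0.0818), Fcer1g (2.49 ± 1.11, adjusted p = 0.136) and Syk (1.07 ± 1.31, adjusted p = 0.600), which myeloid or B cells also use, did not pass. The mean of 11 neutrophil markers lay 3.45 log2 units higher in lymphomas and the list was called by camera (adjusted p = 0.0027; adjusted p = 0.729 with an estimated correlation), with no member passing over all genes and 6 higher adjusted over the list alone. In mPTCL 1, 2, 4, 5, 8 and 9 this mean ran from 8.03 to 12.05, against 5.90 in the highest normal array, and the 18 B cell markers averaged 10.70 to 12.36 in mPTCL 1, 4 and 5, against 9.47. Chil3, a gene of neutrophils and macrophages, rose by 5.81 ± 1.48 (adjusted p = 0.0175; 0.105 without those 6 lymphomas). Macrophage, B cell and hepatocyte lists were not called (camera adjusted p = 0.809, 0.830 and 0.380), and Alb differed by 1.05 ± 0.99 (adjusted p = 0.489). Lymphomas differed in the macrophage mean, which was 9.68, 10.84, 9.82 and 8.96 in mPTCL 1, 4, 5 and 8. In the other lymphomas it ran from 5.76 to 8.24, and in resting cells from 7.59 to 8.42. The remaining genes with the largest increases were Fgl2 (4.90 ± 0.69), Ptgr1 (4.78 ± 0.48), Sulf2 (4.78 ± 0.99) and Spats2 (at least 27.3-fold).

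In limma, 1650 genes were called against resting cells, 836 higher and 814 lower, and camera called 10 of 32 lists. Leaving out resting replicate 1, 2 or 3 left 827, 776 or 806 calls, of which 794, 756 and 778 were among the 1650. Calls lost in each case were those of Chil3 (adjusted p = 0.0593 to 0.0996), Cd4 (0.0907 to 0.101), Cd8a (0.0758 to 0.0898), Id2 (0.0719 to 0.0966), Ifit1 (0.0608 to 0.0663), Ifit3, Runx3, Ets1, Odc1, Sdhb, Slc2a1, Pgam1 and Sh3bp2. Xcl1 was also lost without resting replicate 1 or 3 (0.114 and 0.115), Ndufa4 without resting replicate 1 or 2 (0.0579 and 0.117), Stat5b without resting replicate 1 (0.0521) and Rrs1 without resting replicate 3 (0.0531). Leaving out single lymphomas ended the call of Ifit3 in 7 of 9 cases, Runx3 in 2 and Pgam1 in 1. Without the 6 lymphomas with neutrophil markers, a choice made after seeing the data, 998 of the 1650 calls were kept with 3 lymphomas left. Some calls were lost although the change was larger or less than 10% smaller: Sulf2 (4.35, adjusted p = 0.0906), Spats2 (5.52, 0.0528), Igfbp4 (-5.92, 0.0539), Cd28 (-4.08, 0.0613), Stat5b (-2.25, 0.0780), Cd4 (-4.51, 0.0610), Id2 (1.73, 0.0640), Ifit3 (-1.99, 0.159), Ndufa4 (1.01, 0.0701) and Slc2a1 (1.83, 0.0539). These losses do not tie the genes to the lymphomas left out. The change shrank more in Chil3 (from 5.81 to 3.43, 0.105), Sh3bp2 (0.93, 0.153), Runx3 (0.73, 0.0558), Ifit1 (-2.47, 0.0736), Xcl1 (-1.61, 0.117) and Pgam1 (0.93, 0.0787). With the mean of probe sets Id2 (0.206) and Slc2a1 (0.116) were not called.

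The comparison of the lymphomas with activated T cells addressed how they differ from dividing normal cells. Genes of the TCR and of its signalling were again lower. Of 7 TCR and CD3 genes, 5 fell (6 adjusted over the list alone), with Cd8b1 at -6.13 ± 0.81 log2 units (SE, n = 9 and 3; limma adjusted p = 5.85e-04), Cd8a at -3.95 ± 0.92 and Cd4 at -3.94 ± 1.25, then Cd3d and Cd247 at -2.56 and -2.07. Of 27 proximal TCR signalling genes, 11 fell (13 adjusted over the list alone), with Cd5 at -5.23 ± 0.73, Cd28 at -4.90 ± 0.96 and Cd6 at -4.75 ± 0.78. Genes of naive and quiescent cells fell in 12 of 23 cases (16 adjusted over the list alone), including Ccr7 (-6.24 ± 1.09), Dapl1 (at least 41.1-fold lower) and the cytokine receptor Il6st (-4.24 ± 0.61). Camera adjusted p-values were 0.0018, 9.18e-07 and 3.16e-07 (adjusted p = 0.280, 0.264 and 0.276 with an estimated correlation). Cd3e (-1.43 ± 1.39, adjusted p = 0.482) and Zap70 (-2.15 ± 1.11, adjusted p = 0.184) did not pass, and Bcl11b fell by 2.75 ± 0.88 (adjusted p = 0.0423).

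Of 25 IL-2, IL-15 and JAK-STAT genes, 12 fell (12 adjusted over the list alone), including the receptor gene Il4ra (-3.59 ± 0.57), the kinases Jak3 (-3.08 ± 0.25, adjusted p = 2.34e-05) and Pim2 (-3.02 ± 0.44), and Il2rb (-1.91 ± 0.61). In camera the list had an adjusted p of 3.22e-04 (adjusted p = 0.280 with an estimated correlation). Glycolysis genes were lower in 9 of 15 cases (10 adjusted over the list alone), with Slc16a3 at -3.01 ± 0.42, Pdk1, which keeps pyruvate from the mitochondria, at -2.52 ± 0.52 and Pfkl at -2.18 ± 0.44. For this list, the camera adjusted p was 9.18e-07 (adjusted p = 0.280 with an estimated correlation). Of 25 oxidative phosphorylation genes, 8 rose (8 adjusted over the list alone), with the respiratory chain genes Ndufa4 at 1.73 ± 0.28, Cox7a2 at 1.59 ± 0.20 and Cyc1 at 1.53 ± 0.34. The set test camera returned an adjusted p of 1.30e-08 (adjusted p = 0.345 with an estimated correlation). Of 24 Myc and ribosome biogenesis genes, 17 rose (19 adjusted over the list alone), with Ppan at 2.84 ± 0.40, Srm at 2.45 ± 0.66 and Gnl3 at 2.28 ± 0.24 (adjusted p = 1.32e-04), and a camera adjusted p of 4.24e-10 (adjusted p = 0.404 with an estimated correlation).

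Cell division genes lay near the level of activated cells. Mki67 was at 14.04 ± 0.22 in activated cells (SD, n = 3) and 13.41 ± 0.72 in lymphomas (SD, n = 9; adjusted p = 0.272). Of 29 G2 and M phase genes, Kif23 alone passed, lower by -1.66 ± 0.47 (none adjusted over the list alone). Tested with camera, the list reached an adjusted p of 0.445. The S phase list was called higher by camera (mean 0.78, adjusted p = 4.24e-05; adjusted p = 0.733 with an estimated correlation), with Ung (2.36 ± 0.48) and Fen1 (1.06 ± 0.30) passing of 30 (1 adjusted over the list alone). Srebf2 (-1.49 ± 0.39) and Msmo1 (-1.41 ± 0.37) fell of 19 cholesterol synthesis genes (2 adjusted over the list alone). By camera its adjusted p was 0.0268 (adjusted p = 0.806 with an estimated correlation). That list call was lost without activated replicate 2 (adjusted p = 0.127), mPTCL 4 (0.0579) or mPTCL 5 (0.0757), and without the 6 lymphomas with neutrophil markers (0.788).

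Immediate early genes led by Fos, which rose by 6.70 ± 1.35 (104-fold, adjusted p = 0.0051), Dusp1 (4.31 ± 0.88), Fosb (at least 17.0-fold) and Jun (3.36) rose in 4 of 22 cases (4 adjusted over the list alone). Camera gave the list an adjusted p of 0.0326 (adjusted p = 0.819 with an estimated correlation). The list call was lost without mPTCL 4, 5 or 6 (adjusted p = 0.0666, 0.100 and 0.0923), without the 3 lymphomas with B cell markers (0.186), after quantile normalisation (0.109) and at the signal minimum of 200 (0.0708). The inhibitory receptors Ctla4 and Lag3 fell by 5.08 ± 1.26 and 2.66 ± 0.67 and Tnfrsf4 by 1.66 ± 0.55, while Nr4a1 rose by 2.90 ± 0.69 (1 higher and 2 lower of 22 adjusted over the list alone). In camera the list had an adjusted p of 0.570. Of 20 NK cell receptor and 20 cytotoxic genes, none passed limma, over all genes or adjusted over the list alone (4 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.371 and 0.470; fry 0.479 and 0.647). Klrd1 differed by -3.09 ± 1.63 (adjusted p = 0.192), Klrk1 by -2.06 ± 1.58 (0.367), Ncr1 by 2.93 ± 1.39 (0.149), Gzmb by -1.19 ± 1.66 (0.639) and Zbtb16 by 0.49 ± 0.80 (0.695). Of 17 innate-like and NK transcription regulators, Id2 rose by 1.75 ± 0.39 and Bcl11b, Gata3 and Ets1 (-1.79 ± 0.36) fell, also adjusted over the list alone. For this list, the camera adjusted p was 0.513.

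Of 8 NK receptor adaptors and kinases, Tyrobp rose by 5.91 ± 1.49 (60.3-fold, adjusted p = 0.0147) and Plcg2 by 3.38 ± 0.55 (10.4-fold, adjusted p = 0.0018), with 4 higher adjusted over the list alone. The set test camera returned an adjusted p of 0.0280 (adjusted p = 0.653 with an estimated correlation). Syk (2.07 ± 1.37, adjusted p = 0.299) and Fcer1g (2.89 ± 1.11, adjusted p = 0.0803) did not pass. Myeloid markers moved with them. The neutrophil list was called higher (2 of 11 members, also adjusted over the list alone; camera adjusted p = 0.0015; adjusted p = 0.695 with an estimated correlation), with S100a9 at least 78.9-fold higher (adjusted p = 0.0223) and S100a8 higher by 6.09 ± 1.73 (adjusted p = 0.0253). So was the list of 18 macrophage markers (mean 1.90, no member passing limma and 9 at an unadjusted p under 0.05). Tested with camera, the list reached an adjusted p of 0.0019 (adjusted p = 0.733 with an estimated correlation). Chil3 rose by 7.09 ± 1.45 (136-fold, adjusted p = 0.0054). Without the 6 lymphomas with neutrophil markers the calls of Tyrobp (3.30, adjusted p = 0.228), Plcg2 (2.62, 0.0532), Fosb (3.15, 0.0820), S100a8 (2.21, 0.112) and S100a9 (2.43, 0.0949) and those of the adaptor (0.539), neutrophil (0.299) and macrophage (0.409) lists were lost. So were those of Bcl11b (-2.02, 0.110), Gata3 (-1.62, 0.0903), Srebf2 (-0.86, 0.0963) and Msmo1 (-0.68, 0.130), also with smaller changes. Cd4 (-3.98, 0.0740), Lag3 (-2.99, 0.0704), Il2rb (-1.72, 0.0903) and Pecam1 (-3.22, 0.0509) were lost with changes that were larger or less than 10% smaller. With the mean of probe sets Id2 (0.0949), Fen1 (0.0594) and Kif23 (0.0833) were not called. The adaptor list was also not called without mPTCL 4 (0.0525) or mPTCL 5 (0.0593), without the 3 lymphomas with B cell markers (mean 1.52, 0.186) or at a signal minimum of 200 (0.0528). Without those 3 the macrophage list was not called either (0.0621). Of 11 endothelial and stromal markers, Pecam1 (-3.41 ± 0.77), Col3a1 (-2.34 ± 0.71), Sparc (-2.04 ± 0.62) and Col1a2 (-1.61) fell (5 adjusted over the list alone; camera adjusted p = 0.0268; adjusted p = 0.675 with an estimated correlation), and Alb differed by 0.44 ± 1.00 (adjusted p = 0.784).

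In limma, 1825 genes were called against activated cells, 838 higher and 987 lower, and camera called 14 of 32 lists. The balance depended on the processing, with 1038 higher and 879 lower after quantile normalisation, and 669 and 1181 with the mean of probe sets. Leaving out activated replicate 1, 2 or 3 left 917, 934 or 926 calls, of which 886, 907 and 896 were among the 1825. Calls lost in each case were those of Tyrobp (adjusted p = 0.0603 to 0.0686), S100a8 (0.0846 to 0.0973), S100a9 (0.0827 to 0.0858), Ctla4 (0.0590 to 0.0646), Lag3, Srm (0.0649 to 0.0969), Cd4, Cd3d, Cd247, Bcl11b, Il2rb, Kif23, Fen1, Jun, Srebf2, Msmo1, Tnfrsf4, Col3a1, Col1a2 and Gata3. Cd8a was also lost without activated replicate 1 (0.0541), Nr4a1 without activated replicate 1 or 3 (0.0513 and 0.0606), Id2 likewise (0.0552 and 0.0504), and Sparc without activated replicate 1 or 2 (0.139 and 0.157) or without mPTCL 1, 2, 6 or 8 (0.0503 to 0.0514). Leaving out single lymphomas ended the call of Col1a2 in 8 of 9 cases, Cd247 in 7, Tnfrsf4 in 6 and Bcl11b in 5. It ended those of Cd4, Il2rb and Col3a1 in 4 cases each and that of Fen1 in 2. The median of all genes was -0.08, and 0.08 after quantile normalisation. Across the comparisons no list called by camera kept its call with an estimated correlation, the lowest adjusted p being 0.131, 0.105 and 0.264. The test fry, which asks whether a list moves on balance in 1 direction, called 18, 6 and 10 lists. Against resting cells it did not call the Myc, glycolysis, oxidative phosphorylation, interferon (adjusted p = 0.170) and neutrophil (0.126) lists that camera called. Against activated cells the same held for the S phase (0.188), cholesterol (0.188), immediate early (0.364), macrophage (0.1995) and neutrophil (0.125) lists. The median, mean and test of a list differed in sign for some lists that camera did not call: proximal TCR signalling, cytotoxic, inhibitory receptor, homing receptor and helper T cell genes on activation; p53 target, immediate early, B cell and endothelial genes against resting cells; and inhibitory receptor, erythroid and dendritic cell genes against activated cells. Cd3d, Cd247, Irf9, Slc2a1, Pgam1 and Jun, like Col1a2, fell outside the naming rule and were named after their values were seen.

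**Figure D2:**
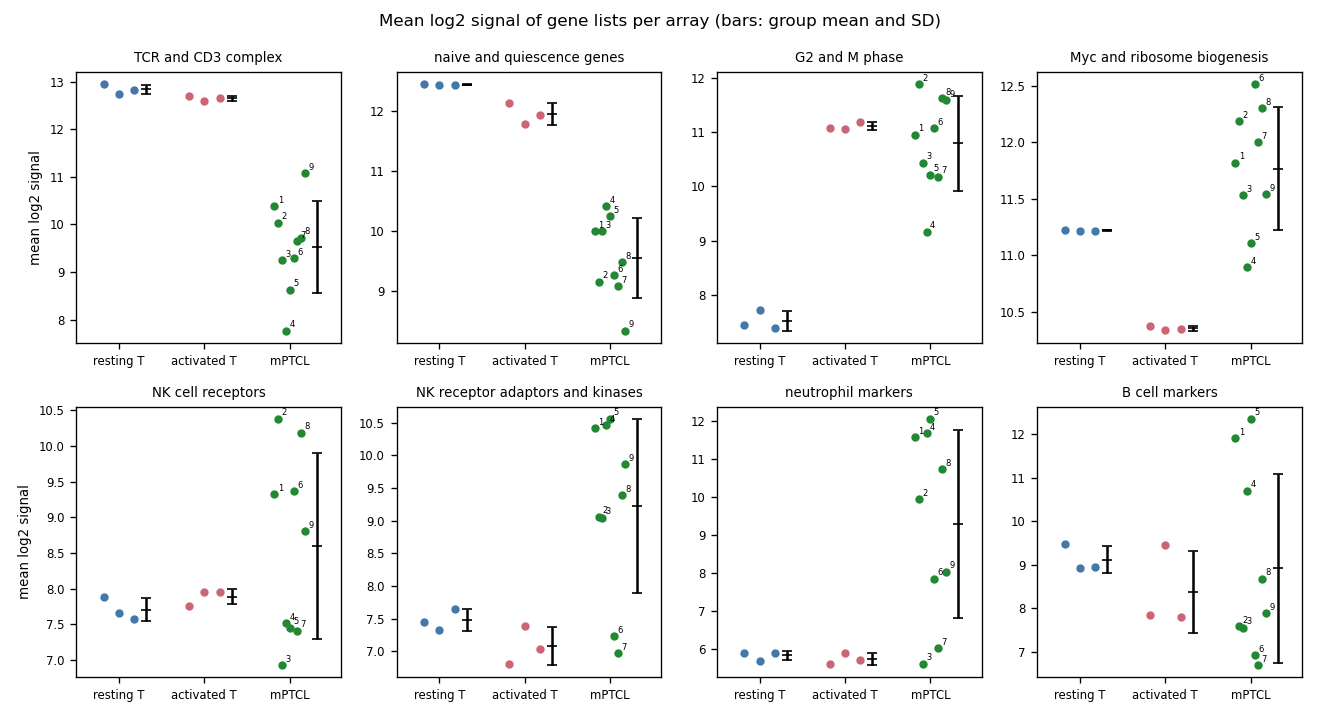
Mean log2 signal of the measured members of 8 gene lists (vertical axis) in each of the 15 arrays, grouped as resting T cells, activated T cells and mPTCL, with points as arrays and bars as mean and SD. The NK cell receptor mean ran from 6.93 to 10.38 among the lymphomas and from 7.58 to 7.96 among the normal arrays, and the neutrophil mean reached 12.05 in the lymphomas against 5.90 in the highest normal array.

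Genes that set the lymphomas apart from both normal states numbered 330 higher and 458 lower. Chil3, Sulf2 and Spats2 were followed among the higher ones by Rai14, Cela1 (3.92 ± 0.78 against resting cells), the calcium-binding S100a4 (3.40 ± 0.99), Plcg2 and the nuclear lamina gene Lmna (3.57 ± 0.82), all of them again higher against activated cells. Lower than both states were Ccr7, Cd8b1, Tdrp, Dapl1, Tmie, Cd5, Cd6 and the RNA transporter gene Sidt1 (-4.84 ± 0.80 against resting cells, adjusted p = 0.0015). Groups below 0 in both comparisons included 5 TCR and CD3 genes, 6 proximal TCR signalling genes, 10 naive and quiescence genes and 6 JAK-STAT genes. No gene was called apart from both states in 50 simulations with unchanged groups and shared lymphomas, and independent lists of these sizes would share 58.8 and 67.4 genes. Each simulation leaves out real effects and the independent lists leave out the shared arrays. With no changes simulated, calls are rare in either comparison, so a count of 0 was nearly certain. The simulations thus cannot show how much the shared lymphomas add to the overlap. The calls of Chil3, Rai14, S100a4 and Lmna were lost on leaving out normal arrays (adjusted p up to 0.0996, 0.0992, 0.116 and 0.0558 against resting cells), that of Spats2 against activated cells without activated replicate 1 (0.0533), and those of Chil3, Sulf2, Spats2 and Rai14 without the 6 lymphomas with neutrophil markers (0.105, 0.0906, 0.0528 and 0.164 against resting cells). Chil3 and Rai14 then changed by less (3.43 and 3.63), while Sulf2 moved from 4.78 to 4.35 and Spats2 from 4.77 to 5.52. Against activated cells Rai14 was also lost without any 1 activated array (up to 0.153), without mPTCL 1, 2, 6, 7, 8 or 9 (0.0543 to 0.0663) and with the mean of probe sets (0.0761). S100a4 and Lmna were lost there without any 1 activated array (up to 0.113 and 0.0881). Plcg2 was not called against activated cells without the 6 lymphomas with neutrophil markers (0.0532). Lmna was not called with the mean of probe sets (0.0545 against resting and 0.100 against activated cells). Counts without a single resting array fell to 209, 183 and 203 higher and to 227, 221 and 240 lower genes. Without a single activated array they fell to 207, 206 and 211 higher and 259, 280 and 270 lower genes.

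In 5 genes, named after their values were seen, the lymphomas were called in opposite directions against the normal states and so lay between them. The lactate exporter Slc16a3 averaged 6.41, 9.26 and 12.27 in resting cells, lymphomas and activated cells, the angiogenic factor Vegfa 5, 7.22 and 9.41, the desaturase Scd2 11.29, 12.72 and 14.31, and phosphoglycerate mutase Pgam1 10.45, 11.49 and 12.56. Ears2 ran the other way, at 8.73, 6.42 and 5, and at a floor of 16 its difference from activated cells was -0.42 (adjusted p = 0.499). Against resting cells Vegfa (adjusted p = 0.0816) and Scd2 (0.154) were not called with the mean of all probe sets of a gene, and against activated cells Ears2 was not (0.760). Leaving out the 6 lymphomas with neutrophil markers ended the calls of Vegfa, Scd2 and Pgam1 against resting cells (0.0733, 0.0947 and 0.0787), with changes of 2.22, 1.58 and 0.93, and those of Vegfa (0.0669) and Scd2 (0.101) against activated cells. Leaving out any 1 resting array ended the calls of Vegfa (0.114 to 0.117), Scd2 (0.0891 to 0.139) and Pgam1 (0.0597 to 0.0758) against resting cells. Leaving out any 1 activated array ended those of Vegfa (0.104 to 0.121), Scd2 (0.0675 to 0.0910) and Ears2 (0.142 to 0.143) against activated cells, and that of Pgam1 was lost without activated replicate 2 or 3 (0.0793 and 0.0560). Ears2 was also lost there without mPTCL 1, 3, 6, 7, 8 or 9 (0.0525 to 0.0716), and Slc16a3 kept its calls in all these fits. Single lymphomas ended other calls: Vegfa against resting cells without mPTCL 6 or 8 (0.0520 and 0.0530), Scd2 without mPTCL 2 (0.0505), and Pgam1 at the 2-fold limit without mPTCL 8 against resting and mPTCL 7 against activated cells.

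The change from resting to activated cells was then set against the change from resting cells to lymphomas over 11920 genes, which are not independent replicates. Pearson's r was 0.42 and Spearman's rho 0.32. Simulated unchanged groups sharing the resting arrays gave an r of 0.44 (range 0.41 to 0.46 over 50 draws) and a rho of 0.41 (0.39 to 0.42). Simulated changes are noise alone, so the shared arrays set their r and rho, and the observed r and rho cannot be judged against them. The covariance was 0.38, against 0.05 in the simulations, a difference of 0.33. Of the 1006 genes higher on activation, 322 were also higher in lymphomas and 20 lower, where independent lists would give 70.6 and 68.7. Of the 504 genes lower on activation, 83 were also lower in lymphomas and 8 higher, where independent lists would give 34.4 and 35.3. Tk1, Cenpf, Mki67 and Slc16a3 rose in both. The 3 resting arrays cannot be divided into parts of at least 2 arrays, so part of the excess over independent lists may come from the shared arrays.

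Each lymphoma's correlation with the mean of each normal state gave no clear order. It averaged 0.807 with resting and 0.805 with activated cells, a mean difference of -0.0022 ± 0.0044 (SD, n = 9; 2-sided exact sign-flip p = 0.172, smallest possible 0.0039), and 3 of 9 lymphomas were nearer to activated cells. Without activated replicate 2 or 3 the exact p was 0.0273 or 0.0234, with lymphomas nearer to resting cells, and with the mean of all probe sets it was 0.0078 (mean difference -0.0080). Without resting replicate 3 the mean difference was 5.47e-04. A mean of 2 arrays is noisier than a mean of 3, which tends to lower its correlations, so these omissions cannot settle the order. The sign-flip test also takes the normal means as fixed and does not measure the spread of the normal arrays.

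The lymphomas differed among themselves in NK cell receptor genes. Their list mean was 10.38 in mPTCL 2, 10.19 in mPTCL 8, 9.37 in mPTCL 6, 9.32 in mPTCL 1 and 8.81 in mPTCL 9, and between 6.93 and 7.51 in mPTCL 3, 4, 5 and 7. It rose with the mean of G2 and M phase genes across the 9 lymphomas (Pearson r = 0.83, exact permutation p = 0.0073; Spearman rho = 0.80, p = 0.0138; r = 0.83 without mPTCL 2 and 3), but not past Benjamini-Hochberg adjustment over the 9 relations computed (adjusted p = 0.0660). With cytotoxic genes r was 0.70 (exact permutation p = 0.0476, adjusted p = 0.143; rho = 0.48, p = 0.194) and 0.53 without mPTCL 2 and 3. The G2 and M phase mean fell with that of naive genes (r = -0.67, exact permutation p = 0.0456, adjusted p = 0.143, and rho = -0.53, p = 0.148). Without mPTCL 2 and 4 this r was -0.52. The last 2 relations were thus weaker without the arrays left out. Without mPTCL 7 these 3 relations passed adjustment (r = 0.81, 0.92 and -0.80; adjusted p = 0.0493, 0.0386 and 0.0493). No relation was detected with 9 lymphomas between NK cell receptor means and those of TCR and CD3 genes (r = 0.52, exact permutation p = 0.156), proximal TCR signalling (r = 0.18, p = 0.661), adaptors (r = -0.03, p = 0.921), inhibitory receptors (r = 0.17, p = 0.666), hepatocyte markers (r = 0.51, p = 0.166) or macrophage markers (r = 0.07, p = 0.857). Single lymphomas moved these values, from 0.06 to 0.69 for proximal TCR signalling, from -0.24 to 0.55 for inhibitory receptors and from -0.34 to 0.11 for adaptors. The labels part the 9 lymphomas into no batches, so no relation could be recomputed within them.

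**Figure D3:**
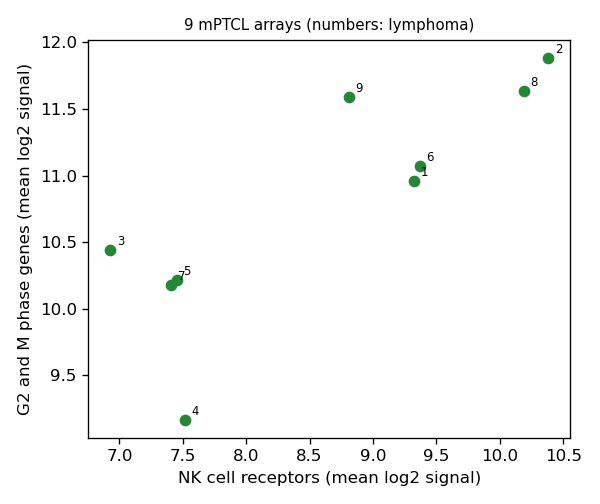
Mean log2 signal of 20 NK cell receptor genes (horizontal axis) against that of 29 G2 and M phase genes (vertical axis) in each of the 9 mPTCL, each point being 1 array. Pearson's r is 0.83, with an adjusted p of 0.0660.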

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

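The tests of other splits of the arrays were chosen before the results were seen, and the tests of RNA from other cells and of the array batch only after.

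Among 205 named genes and list means, 10 had a lymphoma farther from the other 8 than Dixon's limit allows. Chance passes that limit about 1 time in 20, so about this many would pass by chance. In mPTCL 5, Gzma was at 10.45 on the log2 scale (next lymphoma 13.35), Serpinb6b at 8.07 (10.67), Uhrf1 at 10.13 (11.56) and Fas at 9.59 (6.98). In mPTCL 6, Tdrp was at 6.44 (5.17) and Rrm2b at 7.99 (8.92). In mPTCL 4, Col3a1 was at 8.73 (5.40) and the mean of endothelial and stromal markers at 8.36 (6.93). Cr2 was at 8.82 in mPTCL 1 (6.55) and Alb at 11.22 in mPTCL 8 (7.38). Among 4384 probe sets listed with no gene or with several, 81 were higher in lymphomas than in both normal states. No biological explanation was tested for these values.

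Other splits of the arrays into groups of the same sizes called fewer genes in the lymphoma comparisons. Of 100 splits, 1 (the real one) reached 1650 genes against resting cells, where the highest other gave 269. Likewise 1 reached 1825 against activated cells (highest other 167) and 1 reached 788 apart from both states (highest other 29). Such splits mix lymphomas with normal arrays, which widens the spread within groups. They speak only against a chance split of these arrays and cannot tell the group from a batch. For activated against resting cells the 10 splits are too few for a share under 0.05; the real split gave 1510 genes, the highest other 0.

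The mean of TCR and CD3 genes, with the coreceptors among them, was lower in lymphomas than in normal cells. Dilution by RNA of neutrophils, macrophages or B cells was argued against as the whole cause in mPTCL 3 and 7. Their neutrophil means were 5.61 and 6.02, against 5.90 in the highest normal array. Their TCR and CD3 means lay at -3.35 and -2.94 relative to the lowest normal array. Their macrophage (-1.30 and -2.66) and B cell (-1.92 and -2.78) means lay below the highest normal array. The macrophage mean of mPTCL 3, 7.11, still lay above the activated arrays (6.31 to 6.49), and its Chil3 was at 11.26. In mPTCL 7 Cd4, Cd8a and Cd8b1 were at 5, 8.21 and 5.77 but Cd3e at 11.72, so its low mean shows no fall of Cd3e. In mPTCL 6 the TCR and CD3 mean lay at -3.31 with a neutrophil mean of 7.84, and for it and the other 6 lymphomas dilution stays open as a part. A batch of arrays cannot be told apart from the group, since no batch is stated and, parted by whether a software version is stated, 0 sets held both. The difference between lymphoma and normal cells that the design names stays open as untested.

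The NK receptor adaptor list was called higher in lymphomas against activated cells alone (camera adjusted p = 0.0280, 0.653 with an estimated correlation; 0.0598 against resting cells), with 2 of 8 members called in each comparison. Against activated cells the call was lost without the 3 lymphomas with B cell markers (0.186). RNA of neutrophils, macrophages or B cells is a candidate explanation for part of it. The lymphoma cells were sorted, but the gate is not stated and the purity was not tested. Marker RNA stayed high in some, with S100a9 at 13.85, 14.11 and 14.93 in mPTCL 1, 4 and 5, against 6.97 in the highest normal array. Across the 9 lymphomas the list mean rose with that of neutrophil and macrophage markers (r = 0.81, exact permutation p = 0.0072; rho = 0.92, p = 0.0013; r = 0.79 without mPTCL 3 and 7). This mean lay at -0.68 relative to the highest normal array in mPTCL 7, with little of these markers. In mPTCL 6 the adaptor mean lay at -0.42, with a neutrophil mean of 7.84 but a macrophage mean at -1.60 relative to the highest normal array. In mPTCL 3 the adaptor mean lay 1.40 above despite a neutrophil mean of 5.61, with Tyrobp at 12.96 and Chil3 at 11.26. The array batch and the difference between lymphoma and normal cells stay open.

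Plcg2 was higher against both normal states. In mPTCL 3, 6 and 7 it was at 12.73, 11.66 and 10.30, against 10.03 in the highest normal array. RNA of those other cells was weakly argued against as the whole cause of the change against resting cells. That change was 3.15 ± 0.61 in these lymphomas (SE, limma adjusted p = 0.0246). It was 3.10 ± 0.75 in mPTCL 3 and 7, where the call was lost with 2 lymphomas left (0.0598). These lymphomas may not be free of such RNA, since Chil3 was at 11.26 and 11.01 in mPTCL 3 and 6 (highest normal array 7.19). In mPTCL 7, with Chil3 at 7.26, Plcg2 lay above the resting arrays (8.07 to 8.86) but near the highest normal array. Against activated cells the change of 2.62 ± 0.73 passed the same rule of 2 SE above 1, but the argument was still weaker. The call was lost (0.0532), and with mPTCL 3 and 7 alone the change of 2.57 ± 0.91 (0.112) did not pass that rule. The array batch and the difference between lymphoma and normal cells stay open as untested.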

How the results depend on the processing

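Leaving out the lymphomas with neutrophil or B cell markers was chosen only after the data were seen. The cause was not tested for any change below unless the setting itself shows it.

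For named genes, 4208 values under other settings kept direction and side of the threshold, 237 lost the call, 23 gained it and 2 reversed; without single arrays these numbers were 2405, 355, 12 and 0. For lists they were 1505, 62, 28 and 2, and 942, 9, 9 and 0. Ears2 against activated cells reversed at a floor of 16 (-0.42) and with log2 of the value plus 16 (-0.34), since activated cells stood at the floor. Without the 6 lymphomas with neutrophil markers, the macrophage list against resting cells (-1.56, adjusted p = 4.38e-04) and the B cell list against activated cells (-1.32, 0.0261) reversed, because lymphomas carrying those markers were left out.

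With all 15 arrays in 1 fit, activation gave 296 higher and 102 lower genes, as the spread then includes the lymphomas. With the adjusted p alone it gave 1829 and 1847, and 524 genes were higher than both states. Array weights per group gave 1371 higher and 1344 lower genes against resting cells, 1303 and 1646 against activated cells, and 623 and 866 for both states. Without the 3 lymphomas with B cell markers, 601 were higher and 695 lower than both. Lists called numbered 0, 0 and 0 with an estimated correlation, and fry called 6 against resting cells. The relation of the lymphoma change to the activation change was 0.40 with quantile normalisation, 0.39 without the 6 lymphomas and 0.40 without the 3. The difference in similarity was -0.0080 with the mean of probe sets (exact p = 0.0078).

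Without single arrays, activation gave 836 to 1004 higher and 432 to 519 lower genes. Against resting cells the ranges were 450 to 942 and 319 to 916, lowest without resting arrays. Against activated cells they were 466 to 999 and 438 to 1169, lowest without activated arrays. For both states they were 183 to 424 and 221 to 538. Lists called ran from 11 to 13, 10 to 12 and 11 to 14. The relation ran from 0.40 to 0.44 and the similarity difference from -0.0054 to 5.47e-04. Across lymphomas, r ran from 0.77 to 0.89 for NK receptors with G2 and M phase genes, from 0.62 to 0.92 with cytotoxic genes, and from -0.80 to -0.54 for G2 and M phase with naive genes.

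Equal replicate numbers of resting and activated cells did not pair the samples (r of deviations -0.0113, 0.0508 and -0.0078), and not every sample correlated best with its own number. A block for the replicate gave 949 higher and 485 lower genes, 1395 of the 1510 calls shared. With simulated changes of 2 log2 units, 93%, 70% and 69% were recovered, and at 4 log2 units 98%, 99% and 98%, so smaller changes in lymphomas were less often detectable.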

Other observations

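The following genes were chosen after their values were seen. The T cell receptor gamma segment Trgv1 was at 14.71, 14.46 and 13.20 on the log2 scale in mPTCL 3, 4 and 9 and at 11.19 in mPTCL 7, against 7.92 to 9.74 in the normal arrays. Cd163l1, a scavenger receptor gene of gamma-delta T cells, was at 14.41 in mPTCL 3, 12.75 in mPTCL 1 and 12.25 in mPTCL 4, against 7.67 to 10.01 in the normal arrays. The mean of 5 gamma-delta T cell genes was 12.60 in mPTCL 3, 11.50 in mPTCL 4 and 10.10 in mPTCL 1, against 7.54 to 9.00. In mPTCL 9 and 7 it was 8.86 and 7.17, and Cd163l1 stood at the floor in both. The growth factor receptor gene Pdgfrb was at 12.82, 12.20, 9.12, 7.14 and 5.19 in mPTCL 3, 4, 6, 1 and 5 and at the floor of 5 in all 6 normal arrays. The stromal genes Col3a1 and Dcn stood at the floor in mPTCL 3, at 8.73 and 9.45 in mPTCL 4, at 5.40 and 5 in mPTCL 6 and at 5.05 and 6.33 in mPTCL 1. Bgn was at 6.38, 7.61, 6.43 and 5 in mPTCL 3, 4, 6 and 1, against 5 to 7.12 in the normal arrays.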
